A study of Arabidopsis thaliana with 14 samples.

How the data were processed

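Inflorescences holding immature flower buds of stages 1 to 12 were collected from plants in long-day conditions, per the labels' protocols. Cell extracts were taken as total, nuclear and cytoplasmic fractions by a published fractionation method with a cell strainer in place of the usual filter cloth. RNA was extracted with Trizol LS, poly(A)+ RNA was selected with a magnetic bead kit, strand-specific libraries were made with a directional kit, and the multiplexed libraries were sequenced on a HiSeq4000, per the labels' protocols. The labels put the 14 libraries into 6 groups: wild-type Columbia and the mutant aly1-2 in total RNA (3 libraries each), nuclear RNA (2 each) and cytoplasmic RNA (2 each).

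The deposited files gave 1 value per gene for each of the 14 libraries and 1 value per transposable element for the 6 total libraries. The values were estimated counts (expected counts), made by the authors with STAR 2.5.1b and featureCounts of Subread 1.6.1 on TAIR10, per the submitters' processing notes. Some values carried fractions such as 0.50 and 0.33, as when a read with several places is shared among them. How reads with several places were handled is not given in the sources used here. Counting options that appear in stray last lines of the files were not relied on for strand. Between 86.4% and 92.7% of values per library were whole numbers. Genes with shared reads, and genes that overlap in the annotation, are therefore less certain. The counts were neither scaled nor pooled.

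The files held 37336 genes, of which 37051 matched the TAIR10.1 reference by identifier, and 31189 elements. Each element file had 1 other line that names no element, with at most 6 reads, which was left out. Gene names and coordinates came from TAIR10.1, while the files hold no coordinates. Element coordinates were not used here. The planned design assumed whole counts, so the estimated counts were rounded to whole numbers before testing.

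Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) after filterByExpr (minimum count 10, minimum total 15) and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. The total comparison used the 6 total libraries. Nuclear, cytoplasmic, nuclear against cytoplasmic and ratio comparisons came from 1 fit of the 8 fraction libraries with a mean per group. The ratio comparison was the interaction of genotype and fraction. Residual degrees of freedom were 4 in each fit, and the common biological coefficient of variation was 0.179 in the total fit and 0.340 in the fraction fit. Adjusted p-values in the report without another tool's name are from these edgeR fits. SE of a log2 fold change was its size divided by the square root of F. CPM values were TMM-scaled, separately for the total and the fraction libraries. Elements were tested by the same method, with library sizes set by the genes of the same libraries. Where a group had 0 reads, the fold is a lower bound against 3 counts over the group, and where it had 1 to 3 reads the ratio has an exact 95% binomial counting interval.

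The gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. The 22 lists were mRNA export, RNA-directed DNA methylation, maintenance methylation and demethylation, microRNA and post-transcriptional silencing, reporters of lost methylation, floral identity and meristem, flowering time, tapetum and pollen wall, late pollen, meiosis, photosynthesis, heat shock, cold response, touch, wounding and jasmonate, salicylic acid and defense, circadian clock, cell cycle, plastid genome, mitochondrial genome, MIR genes, non-coding RNA genes and cytosolic ribosomal proteins. Of the fixed members, 5 whose symbol did not match the reference were dropped (CLSY2, CLSY3, CLSY4, A6 and HTR10). Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists within a comparison. Gene classes were compared by a two-sided Fisher's exact test.

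Named genes were ALY1 and AGO6 in every comparison and the 10 highest and 10 lowest log2 fold changes among passing genes with a mean log2 CPM of at least 1 and no overlap between groups (the 5 highest and 5 lowest for nucleus against cytoplasm and for elements, which had no level limit). Up to 4 members of each list with the smallest adjusted p were added, with all passing members of the mRNA export and RNA-directed DNA methylation lists. Only some of the genes and elements picked by this rule are printed in the text. List members named for passing adjusted over the list alone, and genes of the chromosome 4 span or of the drought response outside this rule, were chosen after their values were seen.

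The tests were first tested on simulated counts drawn from the real means and library sizes. No replicate pair held identical libraries: the chi-square per degree of freedom between replicates was 5.02 to 34.3. Alternatives were other scalings (RLE size factors, no normalization factors), DESeq2 1.42.0, limma-voom, other filters, organelle and ribosomal RNA genes left out, other sets of libraries in the fit, the replicate number as a block, and each library left out in turn. Robust moderation, the export list without ALY1, and genes called in total RNA read without 1 mutant library of a fraction were added after seeing the data.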

Results

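Poly(A)+ RNA was profiled in immature Arabidopsis flower buds (stages 1 to 12) of wild-type Columbia and of aly1-2, a mutant of ALY1. ALY1 encodes a nuclear RNA-binding protein of the family that links transcription and splicing to mRNA export. Extracts were taken as total, nuclear and cytoplasmic RNA, with 3 total libraries per genotype and 2 nuclear and 2 cytoplasmic libraries per genotype, 14 libraries in all. Gene counts were used for all 14 libraries and transposable element counts for the 6 total libraries.

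Total counts per library, with M for 1e6 counts, ran from 8.76 M to 9.72 M in wild-type total RNA and from 10.24 M to 12.74 M in aly1-2 total RNA. The nuclear libraries held 7.23 M to 8.87 M in wild type and 9.79 M to 11.27 M in the mutant. The cytoplasmic libraries held 9.33 M to 9.67 M in wild type and 7.94 M to 10.65 M in the mutant. Ribosomal RNA took 55.0% ± 7.82 (SD, n = 2) and 52.3% ± 0.0849 (SD, n = 2) of these counts. In total RNA the ribosomal share was 5.60% ± 0.408 in wild type and 5.15% ± 1.66 in aly1-2 (SD, n = 3 each). In nuclear RNA it was 5.05% ± 0.622 in wild type and 5.2% ± 1.11 in aly1-2 (SD, n = 2 each). Counts in the remaining nuclear genes of the cytoplasmic libraries therefore came to 2.1 M to 3.24 M. Plastid transcripts took 15.2% ± 0.0849 of wild-type and 18.5% ± 2.5 of mutant cytoplasmic counts (SD, n = 2 each), against 6.07% ± 0.755 and 5.59% ± 0.508 of the total RNA counts (SD, n = 3 each). In nuclear RNA they took 9.02% ± 0.65 and 10% ± 1.77 (SD, n = 2 each), more than in total RNA. Mitochondrial transcripts took 0.94% to 1.34% of nuclear counts and 0.49% to 0.8% of total RNA counts. The nuclear libraries were thus not free of organelle transcripts. Wild-type nuclear replicate 1 detected 29091 genes and had reads in 1916 of the 6783 genes that were silent in every total library, against 644 to 929 in the other nuclear libraries. The first principal component over 21728 genes held 45% of the variance and the second 13.1%. On the first, the nuclear libraries (−75.1 to −41) lay with the total ones (−52.3 to −34.3) and apart from the cytoplasmic ones (109 to 135.9). Nothing in the labels says that replicates came from separate plants, so the p-values measure the spread between these samples, which may be technical.

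The comparison of total RNA asked which transcripts change when ALY1 is lost. ALY1 itself (AT5G59950, chromosome 5, 24139939 to 24141937 in the TAIR10.1 reference) was at 105, 112 and 119 CPM in the wild-type total libraries and at 14.1, 20.2 and 18.0 CPM in the mutant ones. It fell by 2.69 on the log2 scale (SE 0.15, adjusted p = 0.000319), a 6.45-fold loss. In the nuclear libraries ALY1 was at 66.2 and 33.6 CPM in wild type and 6.34 and 6.20 CPM in aly1-2, and in the cytoplasmic libraries at 48.9 and 50.9 CPM against 19.7 and 14.9 CPM. Every mutant library thus lay below every wild-type library of its kind. ROS1 (AT2G36490, chromosome 2, 15307907 to 15314807 in TAIR10.1), the DNA glycosylase that removes 5-methylcytosine, dropped from 171 ± 17.8 to 13.6 ± 4.72 CPM (SD, n = 3 each; log2 fold change −3.65, SE 0.25, adjusted p = 0.000998). SDC, an F-box gene silenced by DNA methylation in wild type, rose from 0.325 ± 0.203 to 4.16 ± 0.674 CPM (log2 fold change 3.65, SE 0.42, adjusted p = 0.0146), on 9 wild-type and 143 mutant reads. MRD1 rose from 1.36 ± 1.05 to 28.7 ± 1.95 CPM (log2 fold change 4.37, SE 0.34, adjusted p = 0.00244).

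**Figure D1:**
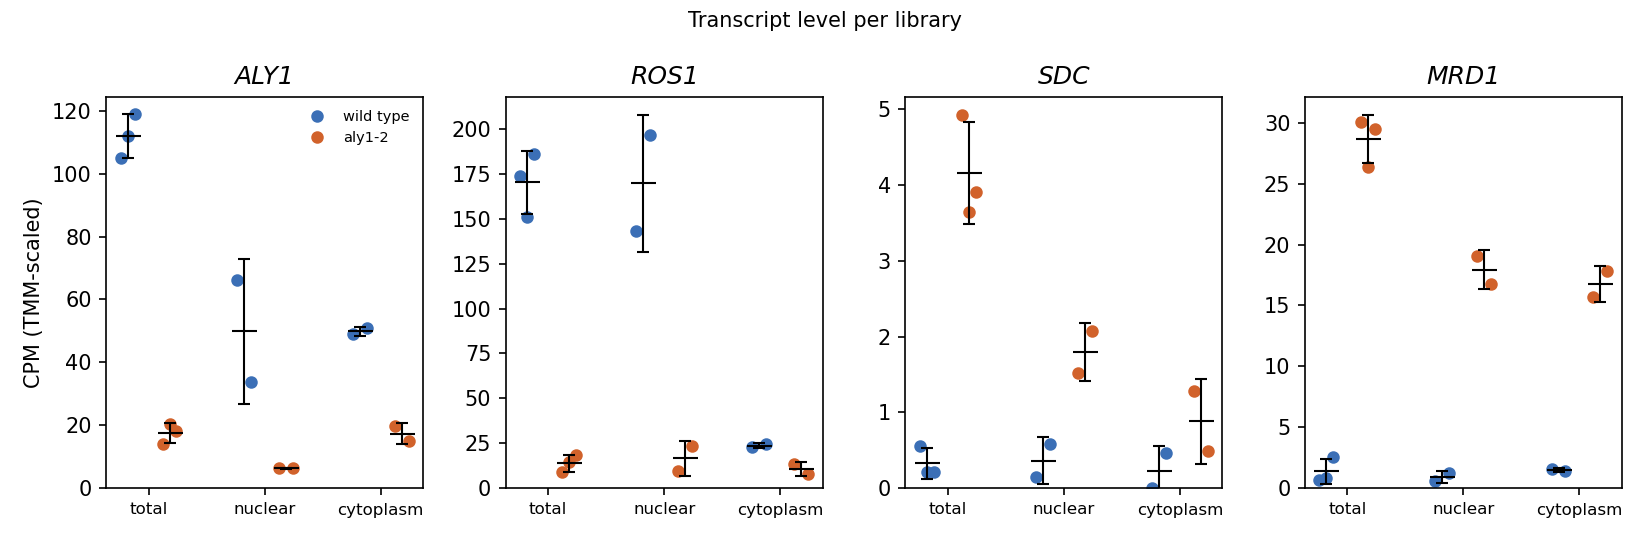
Transcript level (CPM, TMM-scaled) of ALY1, ROS1, SDC and MRD1 in each library of wild type (blue) and aly1-2 (orange), with the mean and SD of each group in black (n = 3 for total, n = 2 for nuclear and cytoplasmic RNA); total and fraction libraries were scaled separately. ROS1 averaged 171 CPM in wild-type and 13.6 CPM in mutant total RNA, and its cytoplasmic means were 23.5 and 10.7 CPM.

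The strongest losses in total RNA came from a single stretch of chromosome 4. SOBER1, a carboxylesterase gene, had 220 wild-type reads and 1 mutant read, a ratio of 265 (95% counting interval 47.1 to 10500; adjusted p = 0.00107 for a log2 fold change of −7.56). Counting intervals and bounds cover counting error only. AT4G22310 dropped from 31.4 ± 3.98 to 0.359 ± 0.254 CPM (log2 fold change −6.42, SE 0.29), AT4G22290 from 6.59 ± 0.477 to 0.114 ± 0.10 CPM (−5.67, SE 0.47) and AT4G22285 from 29.2 ± 3.32 to 1.07 ± 0.322 CPM (−4.74, SE 0.21). AT4G22305, which lies between SOBER1 and AT4G22310 and was chosen after its values were seen because its mean level was below the limit for named genes, had 85 wild-type reads and 0 mutant reads and was thus at least 34.1-fold lower. These 5 genes are the 5 annotated genes between positions 11778749 and 11793137 of chromosome 4 in TAIR10.1, a span of 14.4 kb, and the flanking genes AT4G22280 and AT4G22320 had log2 fold changes of −0.07 (SE 0.28) and 0.17 (SE 0.16). Counts of AT4G22285 were not whole numbers, so part of its reads were shared with other loci, and AT4G22310 overlaps AT4G22320 in the reference, so these values are less certain.

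**Figure D2:**
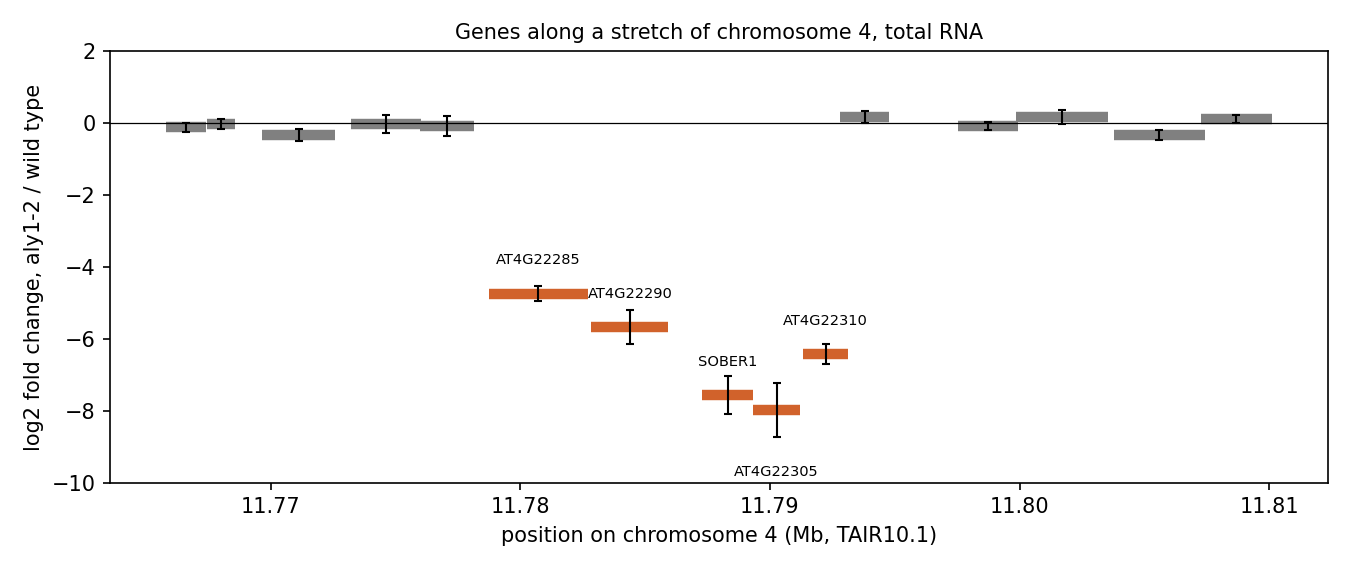
Log2 fold change of aly1-2 over wild type in total RNA (n = 3 each) for the tested genes along a stretch of chromosome 4 (TAIR10.1 coordinates in Mb); bars span the genes and error bars are 1 SE of the edgeR fit. The 5 labelled genes had fitted log2 fold changes from −7.97 (AT4G22305, a fitted value with 0 mutant reads and no bound) to −4.74, and the flanking genes AT4G22280 and AT4G22320 had −0.07 and 0.17.

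Over all genes, 42 rose and 55 fell in total RNA out of 20431 tested (edgeR quasi-likelihood test, adjusted p under 0.05), 36 and 45 of them by over 1 on the log2 scale. Unadjusted p-values under 0.05 numbered 2977, where 1022 would come by chance, and the 3 libraries of each genotype did not overlap for 20% of the genes, against 10% by chance for 3 against 3. Among the risers were the pseudogene AT2G14650 (173 mutant reads and 1 wild-type read, ratio 143, 95% counting interval 25.4 to 5700), AT1G64795 (log2 fold change 5.46, SE 0.51) and the non-coding RNA AT2G01422 (4.50, SE 0.30; 13.9 ± 1.90 against 0.611 ± 0.294 CPM). Pseudogenes made up 9 of the 42 risers although only 151 were tested (two-sided Fisher's exact test, p = 1.87e-11, adjusted p = 2.24e-10 over 24 tests of gene classes). By the same exact test, transcribed pseudogenes gave 3 of 120 (p = 0.00192, adjusted p = 0.0115). Genes annotated as ncRNA gave 4 of 96 (exact p = 4.47e-05, adjusted p = 0.000358). Of 19498 protein-coding genes 26 rose. SOM, a zinc finger gene of seed germination, dropped from 21.0 ± 6.71 to 1.70 ± 0.906 CPM (log2 fold change −3.58, SE 0.38, adjusted p = 0.00976), and AT4G33930 from 54.6 ± 9.48 to 6.28 ± 2.24 CPM (−3.10, SE 0.25). The calls of ALY1, ROS1, MRD1, SOBER1, AT4G22310, AT4G22290, AT4G22285, AT4G33930, AT2G14650 and AT2G01422 held in each of the 6 fits that left out 1 library. The call of AT1G64795 was lost without wild-type replicate 1 (adjusted p = 0.0691), that of SDC without wild-type replicate 2 or 3 or mutant replicate 2 (adjusted p = 0.0957, 0.0658 and 0.0567), and that of SOM without wild-type replicate 1 or 2 or mutant replicate 2 (0.0783, 0.0523 and 0.0529). The call of AT4G22305 was lost without any wild-type replicate or mutant replicate 2 (adjusted p = 0.0549 to 0.13). Among other called genes, AT1G61920 (higher) and AT3G10815 (lower) lost their calls in 5 of the 6 fits. AT3G28899 (higher), AT3G19920 and AT5G35935 (both lower) lost theirs in 4. Without mutant replicate 1 the count of called genes was 1639, and it was 16, 22 and 40 without wild-type replicates 1, 2 and 3 and 25 and 49 without mutant replicates 2 and 3. On simulated total libraries the same test recovered 44.8% of genes changed 2-fold and 83.4% of those changed 4-fold. Over 2 such runs a mean of 10.5 of 99 calls were false, a higher share than the threshold of 0.05 aims at.

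Small groups of stress genes stood higher in mutant total RNA. In the cold response list 7 of 7 genes had a positive fold change (median log2 0.63; camera adjusted p = 0.000153, and adjusted p = 0.435 with an estimated correlation). CBF3, a transcription factor of cold acclimation, rose from 1.85 ± 0.542 to 5.91 ± 0.625 CPM (log2 fold change 1.67, SE 0.27, adjusted p = 0.05 after rounding up), and 5 genes passed when adjusted over the list alone, among them CBF2 (0.91, SE 0.28) and KIN1 (0.63, SE 0.15). In the salicylic acid and defense list 7 of 8 genes were positive (median 0.60; camera adjusted p = 0.000153, and adjusted p = 0.278 with an estimated correlation). PAD4, a lipase-like regulator of defense, rose from 1.74 ± 0.385 to 6.0 ± 1.41 CPM (log2 fold change 1.77, SE 0.29, adjusted p = 0.05 after rounding up), and 5 genes passed when adjusted over the list alone, including WRKY70 (0.65, SE 0.13), EDS1 (0.55, SE 0.16) and PR5 (0.96, SE 0.29). Both calls over all genes were lost without any 1 of wild-type replicates 1, 2 and 3 and mutant replicates 2 and 3, with adjusted p from 0.114 to 0.223 for CBF3 and 0.108 to 0.223 for PAD4. Without mutant replicate 1, KIN1 (adjusted p = 0.007), COR47 (0.044), WRKY70 (0.0213), EDS1 (0.00662), AG (0.0103) and ELF4 (0.0162) passed over all genes. So did the clock gene PRR9 (log2 fold change −3.16, adjusted p = 0.00543) and the pollen coat gene GRP17 (1.17, adjusted p = 0.00425). Floral identity and meristem genes were positive in 15 of 19 cases (median 0.31; camera adjusted p = 0.0036, and adjusted p = 0.508 with an estimated correlation), with no gene passing over all genes and AG (0.66, SE 0.14) passing when adjusted over the list alone. Photosynthesis genes were positive in 13 of 14 cases (median 0.24; camera adjusted p = 0.0485, and adjusted p = 0.893 with an estimated correlation), none passing either way. Their mean deviation was 0.62 in mutant replicate 1 and −0.30 to 0.12 in the other 5 total libraries. Circadian clock genes went the other way, with 3 of 12 positive (median −0.20; camera adjusted p = 0.0496, and adjusted p = 0.705 with an estimated correlation), and ELF4 (−0.62, SE 0.12) alone passed when adjusted over the list alone. The clock list's mean deviation was 0.20, 0.46 and −0.03 in wild-type replicates 1 to 3 and 0.20, −0.59 and −0.24 in the mutant ones, so the genotypes overlapped. Fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, passed for the salicylic acid and defense list (adjusted p = 0.0317). It did not pass for the cold (0.0751), floral (0.097), photosynthesis (0.669) or clock list (0.433).

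Few genes of mRNA export and DNA methylation passed in total RNA. ALY1 was the only gene of 24 in the mRNA export list to pass, over all genes and adjusted over the list alone (camera adjusted p = 0.0619); its paralogs ALY2, ALY3 and ALY4 had log2 fold changes of −0.08 (SE 0.09), −0.08 (SE 0.09) and −0.24 (SE 0.09). The export list was lower by fry (adjusted p = 0.0317; camera adjusted p = 0.435 with an estimated correlation), but not with ALY1 left out (fry adjusted p = 0.451, camera 0.699), a setting chosen after seeing the data. The other 23 genes had a median of −0.07, and their mean deviation was 0, 0.06 and 0 in wild-type replicates 1 to 3 and 0.01, −0.04 and −0.03 in the mutant ones. AGO6, an Argonaute of RNA-directed DNA methylation, was at 2.85 ± 0.476 CPM in the mutant and 2.34 ± 0.986 CPM in wild type (SD, n = 3 each; log2 fold change 0.28, SE 0.35, adjusted p = 0.738). Of 30 tested genes of RNA-directed DNA methylation 1 rose, both over all genes and adjusted over the list alone: AGO9, from 74.9 ± 6.03 to 123 ± 7.67 CPM (log2 fold change 0.72, SE 0.10, adjusted p = 0.0357; 0.0996 to 0.191 without any wild-type replicate or mutant replicate 2 or 3), with camera adjusted p = 0.0666 and fry adjusted p = 0.0751 for the list. Of 18 genes of maintenance methylation and demethylation only ROS1 changed (camera adjusted p = 0.842), and DML2, another demethylase gene, had 0.47 (SE 0.15, adjusted p = 0.213, and 0.0129 without mutant replicate 1). ROS1 was also the 1 call adjusted over the list alone. The 3 tested reporters of lost methylation held SDC, which rose, and ROS1, which fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0629), while QQS had −0.40 (SE 0.42). Since SDC and ROS1 moved opposite ways, a test for 1 direction does not summarize this list. No gene of the microRNA and post-transcriptional silencing list passed over all genes or adjusted over the list alone (0 of 14; camera adjusted p = 0.982).

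The remaining lists did not pass in total RNA by camera. Adjusted p was 0.595 for flowering time, 0.121 for tapetum and pollen wall, 0.641 for late pollen, 0.147 for meiosis, 0.147 for heat shock, 0.595 for touch, wounding and jasmonate, 0.166 for cell cycle, 0.652 for the plastid genome, 0.699 for the mitochondrial genome, 0.794 for non-coding RNA genes and 0.0619 for cytosolic ribosomal proteins. Of these, the meiosis list passed fry as higher (adjusted p = 0.0436), and the others had fry adjusted p of 0.177 to 0.879. Fry did not pass for the reporter (0.097), maintenance methylation (0.876) or microRNA list (0.975). Adjusted over the list alone, DMC1 (0.89, SE 0.18) and HEI10 (0.87, SE 0.20) of 8 meiosis genes, WRKY40, JAZ5 and LOX3 of 10 touch and jasmonate genes, and 2 lower mitochondrial genes of 63 passed, against 0 over all genes in each list. Of 478 non-coding RNA genes 4 rose over all genes, while 8 were higher and 2 lower adjusted over the list alone; AT4G04223 went from 3.20 ± 0.771 to 24.8 ± 0.285 CPM. Of 315 ribosomal protein genes 1 rose, AT1G33850 (log2 fold change 4.48, SE 0.53). Its call was lost without any wild-type replicate or mutant replicate 2 (adjusted p = 0.0549 to 0.133). The MIR rule found 0 genes in the annotation used. Median, mean and test differed in sign for maintenance methylation (median 0.09, mean −0.09, test lower), touch (median −0.05, mean −0.02, test higher), microRNA (median −0.01, mean −0.02, test higher) and non-coding RNA genes (median −0.02, mean 0.03, test higher). Heat shock genes varied widely within genotypes: their mean log2 deviation was −2.02, 1.63 and −0.96 in wild-type replicates 1 to 3 and 1.46, −0.70 and 0.59 in the mutant ones.

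Transposable elements were counted in the total libraries to ask whether silenced sequences gain transcripts in the mutant. Of 854 elements tested, 66 rose and 12 fell (edgeR quasi-likelihood test with gene-based library sizes, adjusted p under 0.05), with 172 at an unadjusted p under 0.05 where 43 would come by chance. AT1TE75440 had 0 wild-type and 83 mutant reads and was at least 22.5-fold higher, at 2.39 ± 0.847 CPM in the mutant. AT3TE76405 had 0 wild-type and 55 mutant reads and was at least 14.9-fold higher. Among those that fell, AT2TE24525 went from 10.2 ± 4.59 to 1.06 ± 1.11 CPM (log2 fold change −3.20, SE 0.58, adjusted p = 0.0057) and AT4TE04425 from 5.02 ± 0.971 to 0.754 ± 0.620 CPM (−2.67, SE 0.52, adjusted p = 0.00847). AT1TE09960 (−2.23, SE 0.58) and AT2TE86100 (−1.99, SE 0.49) also fell, but each lost its call in 5 of the 6 fits that left out 1 library. Of the risers, 5 had no wild-type read. The share of element counts relative to gene counts was 1.5% ± 0.0640 in aly1-2 and 1.41% ± 0.0880 in wild type (SD, n = 3 each), and 61.8% of tested elements had a positive fold change (median log2 0.12). Scaling on the elements themselves gave 59 risers and 20 fallers. The count was 155 without mutant replicate 1 and 51 without mutant replicate 2.

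**Figure D3:**
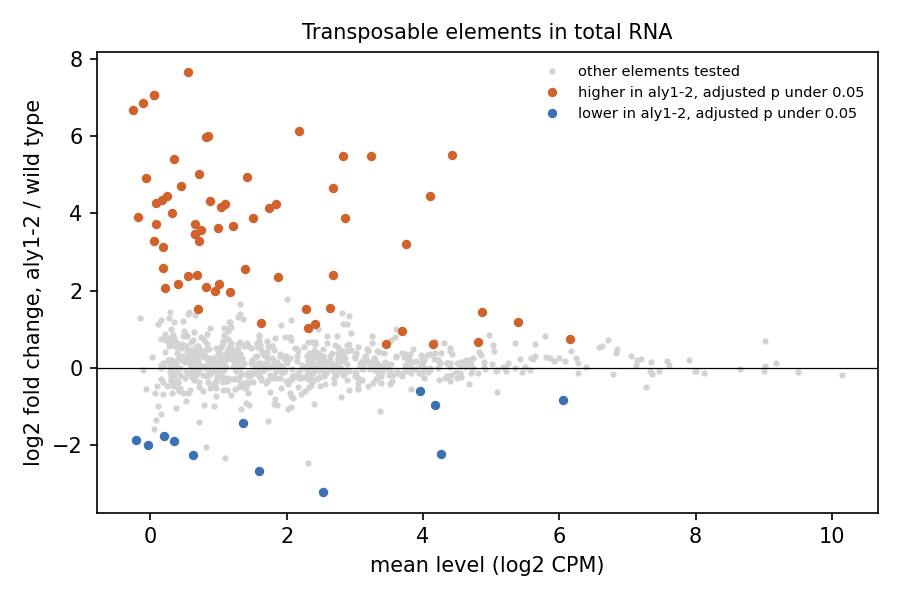
Log2 fold change of aly1-2 over wild type (n = 3 each) against the mean level (log2 CPM) for the 854 transposable elements tested in total RNA; each point is an element. The 66 elements that rose are in orange and the 12 that fell in blue.

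Nuclear RNA was compared to ask which transcripts differ in the nucleus of the mutant. ALY1 fell by 2.99 on the log2 scale (SE 0.38, adjusted p = 0.0121) and ROS1 dropped from 170 ± 38.3 to 16.5 ± 9.83 CPM (SD, n = 2 each; log2 fold change −3.37, SE 0.44, adjusted p = 0.0123). The chromosome 4 genes AT4G22310 (414 wild-type and 3 mutant reads, ratio 159, 95% counting interval 54.0 to 774) and AT4G22285 (log2 fold change −4.62, SE 0.50) fell, as did AT4G33930 (−2.71, SE 0.42). MRD1 rose from 0.897 ± 0.453 to 17.9 ± 1.62 CPM (4.29, SE 0.46, adjusted p = 0.00295), with AT5G35205 (3.93, SE 0.57) and AT5G23115 (308 mutant reads and 1 wild-type read, ratio 267, interval 47.6 to 10600). These were the 3 genes that rose and the 5 that fell of 20971 tested (edgeR quasi-likelihood test, with 474 genes at an unadjusted p under 0.05 where 1049 would come by chance), and all 8 were also called in total RNA. Scaling by RLE size factors gave 5 and 5. SDC had a log2 fold change of 2.26 (SE 1.08) and AGO6 of −0.42 (SE 1.27, on 20 mutant and 24 wild-type reads), neither passing. The 42 genes that rose in total RNA had a median of 2.41 in nuclear RNA and 40 of them were positive (camera p = 3.7e-05 with an estimated correlation), and all 55 that fell were negative (median −1.55, p = 0.00204). Total and fraction libraries may come from the same plants, which the labels do not say, so these are not independent tests. Deviations from the group mean of same-numbered total and nuclear libraries correlated across genes at 0.704 and 0.393 in the mutant and 0.082 and 0.033 in wild type. Without mutant nuclear replicate 1 or 2, settings chosen after seeing the data, 40 of 42 and 40 of 41 risers were positive and all 55 fallers negative.

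The largest group difference in nuclear RNA was in heat shock genes. All 9 had positive fold changes in the mutant (median log2 2.28; camera adjusted p = 3.52e-13, and adjusted p = 0.291 with an estimated correlation), with 0 passing over all genes and 8 when adjusted over the list alone, among them HSP101 (2.12, SE 0.53) and HSP90.1 (2.28, SE 0.69). The mean deviation for the list was 2.73 in mutant nuclear replicate 1, 0.31 in mutant replicate 2 and −0.51 and −0.12 in wild type. Without mutant nuclear replicate 2, HSP101 (adjusted p = 0.00172) and HSP90.1 (0.00527) passed over all genes. All 14 photosynthesis genes were positive (median 0.45; adjusted p = 4.94e-07, and adjusted p = 0.369 with an estimated correlation), 3 passing when adjusted over the list alone, including LHCB1.2 (1.33, SE 0.35). Mutant nuclear replicate 1 had a mean deviation of 0.42 for this list, against −0.58 to −0.24 in the other 3 nuclear libraries. Cold response genes (median 0.67; adjusted p = 0.00408, and adjusted p = 0.369 with an estimated correlation) and salicylic acid and defense genes (median 0.52; 0.0127, and adjusted p = 0.291 with an estimated correlation) were higher as lists. Floral identity genes were also higher (median 0.25; 0.0285, and adjusted p = 0.473 with an estimated correlation). These 3 lists had 0 genes passing over all genes or adjusted over the list alone. Plastid transcripts were lower with 0 members passing either way (42 of 126 positive, median −0.12; adjusted p = 0.000615, and adjusted p = 0.291 with an estimated correlation). Their mean deviation was −0.24 and −0.64 in wild-type nuclear replicates 1 and 2 and −0.71 and −0.66 in the mutant ones, so wild-type replicate 2 lay close to the mutant libraries. Their share of nuclear counts went the other way, at 9.02% ± 0.65 in wild type and 10% ± 1.77 in the mutant (SD, n = 2 each). The list of 4 methylation reporters was also lower by camera (median −0.40; adjusted p = 0.0127, and adjusted p = 0.291 with an estimated correlation). ROS1 alone of these passed, both ways, and SDC, at 2.26, had the opposite sign without passing. A test for 1 direction does not summarize such a list. No list passed fry in nuclear RNA, where the lowest adjusted p was 0.575.

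With 2 libraries per group the nuclear test was weak: on simulated libraries it recovered 1.5% of genes changed 2-fold and 31.8% of those changed 4-fold. There a mean of 2.5 of 24.5 calls were false. The count of 8 genes became 3 without wild-type nuclear replicate 1, 157 (22 higher, 135 lower) and 34 (29 higher, 5 lower) without mutant nuclear replicates 1 and 2, and 4 without either wild-type cytoplasmic library, which share the fit. AT4G22310 and AT4G22285 kept their calls in each of the 8 fits. ALY1 and ROS1 lost theirs without wild-type cytoplasmic replicate 1 or 2 (adjusted p = 0.0801 to 0.0826), ALY1 (0.077) and MRD1 (0.0651) without wild-type nuclear replicate 1. AT4G33930, AT5G35205 and AT5G23115 also lost theirs without wild-type nuclear replicate 1 (adjusted p = 0.804, 0.758 and 0.539). So did AT4G33930 without any cytoplasmic library (0.102 to 0.127), AT5G35205 without wild-type cytoplasmic replicate 1 or 2, wild-type nuclear replicate 2 or mutant nuclear replicate 2 (0.0801 to 0.122), and AT5G23115 without wild-type nuclear replicate 2 (0.0904).

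Cytoplasmic RNA was compared to ask which transcripts differ in the cytoplasm of the mutant. MRD1 rose from 1.47 ± 0.135 to 16.8 ± 1.49 CPM (SD, n = 2 each; log2 fold change 3.50, SE 0.48, adjusted p = 0.0346), and AT4G22310 (−5.27, SE 0.66, adjusted p = 0.0328) and AT4G22285 (−4.18, SE 0.55, adjusted p = 0.0328) fell. These were the 3 genes past the threshold of 20971, and each was also called in total RNA (edgeR quasi-likelihood test, 1907 at an unadjusted p under 0.05). ALY1 was at 17.3 ± 3.38 against 49.9 ± 1.42 CPM (log2 fold change −1.52, SE 0.37, adjusted p = 0.369), and passed only when adjusted over its list alone. ROS1 was at 10.7 ± 3.90 against 23.5 ± 1.27 CPM (−1.12, SE 0.43, adjusted p = 0.477), and AGO6 had 1 mutant and 11 wild-type reads (ratio 9.83, 95% counting interval 1.43 to 423), all 11 in wild-type replicate 1. The 42 genes that rose in total RNA were positive in 35 cases (median 1.66; camera p = 0.000785 with an estimated correlation), and the 55 that fell negative in 51 (median −1.22, p = 0.0364). Same-numbered total and cytoplasmic libraries correlated at 0.245 and 0.168 in the mutant and 0.083 and 0.015 in wild type. Without mutant cytoplasmic replicate 1 or 2 the risers were positive in 31 and 32 cases (medians 0.99 and 1.51) and the fallers negative in 53 and 46. Plastid transcripts were higher in mutant cytoplasm (95 of 126 positive, median 0.40; camera adjusted p = 3.59e-05, and adjusted p = 0.401 with an estimated correlation), as were photosynthesis genes (14 of 14, median 0.51; 0.000288, and adjusted p = 0.737 with an estimated correlation). Heat shock genes were higher (9 of 9, median 1.72; 0.00522, and adjusted p = 0.737 with an estimated correlation), as were tapetum and pollen wall genes (12 of 15, median 0.74; 0.0053, and adjusted p = 0.737 with an estimated correlation). No gene of these 4 lists passed over all genes; adjusted over the list alone, LHCB1.2 and the pollen coat gene GRP17 did, and 0 plastid or heat shock genes. No list passed fry (lowest adjusted p = 0.493). Heat shock genes deviated by 1.32 in mutant cytoplasmic replicate 1, by −1.50 in replicate 2 and by −1.48 and −0.76 in wild type, so only mutant replicate 1 lay above the wild-type libraries. Without any 1 of the 4 cytoplasmic libraries the count of 3 became 0, with adjusted p of 0.123 to 0.477 for MRD1 and 0.123 to 0.364 for AT4G22310 and 0.139 to 0.364 for AT4G22285. The count was 46 and 52 without mutant nuclear replicates 1 and 2. AT4G22285 also lost its call without wild-type nuclear replicate 1 (0.0795) or 2 (0.0729). The simulated test recovered 18.6% of genes changed 4-fold and 0% of those changed 2-fold, with a mean of 1 false call among 13.5.

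The nuclear to cytoplasmic ratio was compared between genotypes to ask which transcripts are retained in or depleted from the nucleus when ALY1 is lost. No gene passed out of 20971 (edgeR 0, DESeq2 0, limma-voom 0), with 705 at an unadjusted p under 0.05, where 1049 would come by chance. ROS1 had the ratio lower by a log2 difference of −2.25 (SE 0.60), passing only when adjusted over the maintenance or reporter list alone. AGO6 had a difference of 2.81 with an SE of 2.38, so neither retention nor its absence was detectable at this depth, and ALY1 had −1.47 (SE 0.51). The plastid list had a lower ratio in the mutant (31 of 126 positive, median −0.62; camera adjusted p = 1.62e-11, and adjusted p = 0.123 with an estimated correlation), with 0 of its genes passing over all genes or adjusted over the list alone. Fry gave adjusted p = 0.463 for it, the lowest of the lists. The count of 0 became 1 without wild-type nuclear replicate 2 and 3 without mutant nuclear replicate 1. The test recovered 2.26% of simulated genes with a 4-fold change of the ratio, with a mean of 1 false call among 4, and the median SE was 0.699.

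Within wild type the fractions separated transcripts by kind, with changes given relative to the typical gene. Since nuclear libraries also held organelle transcripts, a higher level there is not read as location in the nucleus. The demethylase genes DME (log2 nucleus over cytoplasm 3.02, SE 0.38), DML3 (3.91, SE 0.56) and ROS1 (2.86, SE 0.43) were higher in the nucleus, with AGO4 (2.42, SE 0.32) and AGO9 (2.47, SE 0.35), the RNA-dependent RNA polymerase gene RDR6 (3.51, SE 0.48), the export gene SAC3B (3.06, SE 0.42), the flowering repressor MAF2 (2.89, SE 0.40) and GRP17 (2.82, SE 0.42). The clock gene LHY (−2.77, SE 0.46) and the cytokinesis syntaxin KN (−1.99, SE 0.33) were higher in the cytoplasm, with the plastid genes ATCG00080 (−5.17, SE 0.45) and ATCG00650 (−4.66, SE 0.38). These calls held in each of the 8 fits that left out 1 library, but those of other genes did not. DCL3, higher in the nucleus, lost its call in 6 of the 8 fits. Of the export genes, EER5, TEX1, THO6 and THO7B were higher in the cytoplasm and each lost the call in 3 fits. MOS11 and NUP160, higher in the nucleus, also lost theirs in 3, and THO2 and THO5A in 1. ALY1 averaged 49.9 CPM in both fractions, with its nuclear libraries at 66.2 and 33.6 CPM and its cytoplasmic ones at 48.9 and 50.9 CPM. In all, 2318 genes were higher in the nucleus and 1685 in the cytoplasm of 20971. With no normalization factors the split was 12211 and 101, since the median of all genes then moved from 0.053 to 1.64.

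As groups in wild type, mitochondrial transcripts (68 of 73 positive, median 2.30; camera adjusted p = 3.02e-11, and adjusted p = 0.268 with an estimated correlation), non-coding RNA genes (median 0.87; 0.000108, and adjusted p = 0.209 with an estimated correlation), and maintenance methylation genes (median 1.19; 0.000261, and adjusted p = 0.268 with an estimated correlation) were higher in the nucleus. So were tapetum genes (median 1.64; 0.000775, and adjusted p = 0.274 with an estimated correlation), RNA-directed DNA methylation genes (median 0.42; 0.0344, and adjusted p = 0.274 with an estimated correlation) and microRNA pathway genes (median 0.89; 0.0298, and adjusted p = 0.268 with an estimated correlation). Adjusted over the list alone, 33, 113, 10, 10, 8 and 3 of their members were higher in the nucleus, against 27, 104, 7, 9, 8 and 3 over all genes. Plastid transcripts (median −0.26; 1.36e-05, and adjusted p = 0.209 with an estimated correlation), ribosomal protein genes (median −0.35; 0.000108, and adjusted p = 0.501 with an estimated correlation) and cold response genes (median −0.73; 0.0471, and adjusted p = 0.501 with an estimated correlation) were lower. With no normalization factors these 3 medians were 1.36, 1.22 and 0.88, below the median of all genes (1.64) as under TMM scaling. Adjusted over the list alone 42, 46 and 1 of their members were lower, against 40, 48 and 1 over all genes. By fry the first 6 lists and the plastid list passed (adjusted p = 0.00104 to 0.012), and the ribosomal protein and cold lists did not (0.0565 each). Of 24 tRNA genes 13 were lower in the nucleus. The count of 4003 genes was 2048 and 2140 without wild-type nuclear replicates 1 and 2 and 2350 and 1610 without wild-type cytoplasmic replicates 1 and 2.

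In aly1-2 the same contrast gave 2338 genes higher in the nucleus and 1636 higher in the cytoplasm, and 12253 and 149 with no normalization factors, where the median of all genes moved from 0.108 to 1.64. DME (2.55, SE 0.37), SAC3B (3.06, SE 0.42) and MAF2 (3.43, SE 0.41) were higher in the nucleus and LHY (−3.66, SE 0.48) and ATCG00080 (−6.33, SE 0.47) in the cytoplasm. The remaining ALY1 transcript was lower in the nucleus (log2 ratio −1.47, SE 0.37, adjusted p = 0.0167), and at 0.06 with no normalization factors, again below the median of all genes. Its adjusted p was 0.0597 without mutant nuclear replicate 2 and 0.128 without mutant cytoplasmic replicate 1. ROS1 had 0.60 (SE 0.43, adjusted p = 0.338). For ALY1 and ROS1 the difference of this ratio between genotypes did not pass over all genes. The mitochondrial (camera adjusted p = 8.88e-11, and adjusted p = 0.441 with an estimated correlation), non-coding RNA (6.26e-06, and adjusted p = 0.089 with an estimated correlation), and maintenance methylation lists (0.0173, and adjusted p = 0.468 with an estimated correlation) were higher in the nucleus. So were the microRNA pathway (0.0175, and adjusted p = 0.284 with an estimated correlation) and tapetum lists (0.0209, and adjusted p = 0.504 with an estimated correlation). Plastid transcripts (median −1.20; 3.2e-16, and adjusted p = 0.0666 with an estimated correlation) and ribosomal protein genes (median −0.50; 1.56e-07, and adjusted p = 0.441 with an estimated correlation) were lower, with medians of 0.35 and 1.04, again below that of all genes, when no normalization factors were used. Adjusted over the list alone, 27 mitochondrial, 121 non-coding RNA, 8 maintenance, 4 microRNA pathway and 6 tapetum genes were higher in the nucleus and 61 plastid and 60 ribosomal protein genes lower. Over all genes these counts were 24, 110, 7, 4 and 4, and 52 and 59. These 7 lists also passed fry (adjusted p = 0.00175 to 0.0317), as did the RNA-directed DNA methylation list as higher in the nucleus (0.0102). Across genes, which are not independent replicates, the log2 ratios of the genotypes correlated with r = 0.675 (Spearman's rho 0.745). Both genotypes placed 1589 genes higher in the nucleus (258 expected of independent lists) and 1058 higher in the cytoplasm (131 expected), and 0 genes in opposite fractions. The count of 3974 was 1996 without mutant nuclear replicate 2 and 1767 and 2008 without mutant cytoplasmic replicates 1 and 2.

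**Figure D4:**
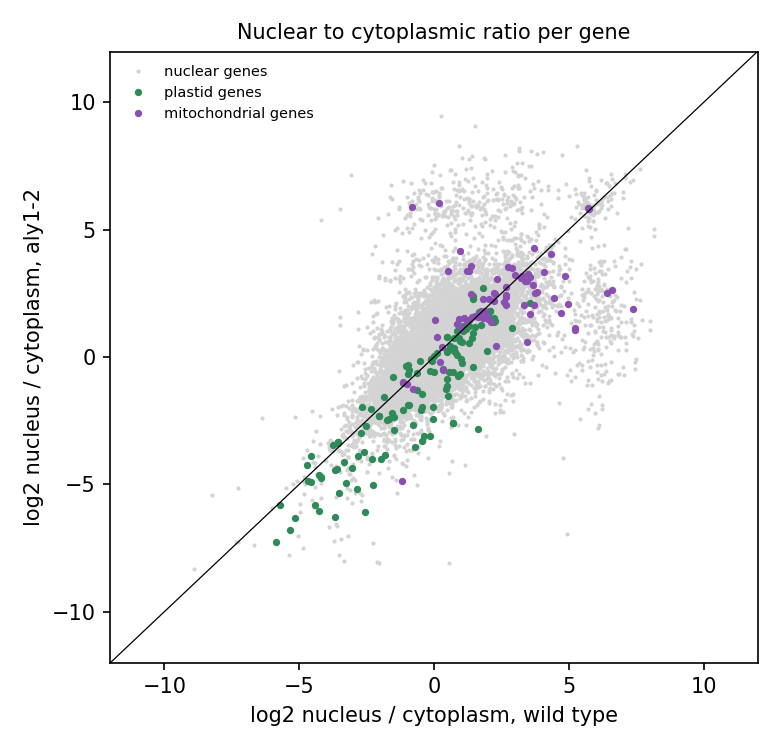
Log2 ratio of nuclear to cytoplasmic RNA per gene in wild type (x axis) and aly1-2 (y axis), n = 2 libraries per group; each point is a gene of the 20971 tested, with plastid genes in green, mitochondrial genes in purple and the diagonal in black. Relative to the typical gene under TMM scaling, mitochondrial genes had medians of 2.30 and 2.28, and plastid genes of −0.26 and −1.20, which became 1.36 and 0.35 with no normalization factors, where the median of all genes was 1.64 in each genotype.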

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

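The tests of both chromosome 4 explanations, of 1 mutant library alone, of shared reads in elements without whole values, of background reads as the source of the elements that rose, and all 3 on mutant total replicate 1 were chosen only after the result was seen.

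The nuclear to cytoplasmic ratio of plastid transcripts differed between the genotypes as a list, by a median log2 difference of −0.62, with 31 of 126 genes positive. This passed camera with the preset correlation (adjusted p = 1.62e-11) and not with an estimated one (adjusted p = 0.123). The list's mean log2 CPM was 4.18 and 3.77 in wild-type nuclear, 3.7 and 3.75 in mutant nuclear, 4.69 and 4.86 in wild-type cytoplasmic and 5.08 and 5.27 in mutant cytoplasmic libraries. Wild-type nuclear replicate 2 thus lay close to the mutant nuclear libraries, and the nuclear side rested on wild-type nuclear replicate 1. The cytoplasmic libraries of the genotypes did not overlap.

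The 5 neighbouring genes on chromosome 4 all passed as lower in total RNA. Their log2 fold changes were also negative in nuclear (−8.24 to −4.62) and cytoplasmic RNA (−8.04 to −3.73), where only AT4G22310 and AT4G22285 passed. Reads shared with near-identical copies are argued against for the 3 of the 5 genes that had whole values in all 3 wild-type total libraries and still fell by over 2 on the log2 scale. A deletion or rearrangement in the mutant line stays open: the highest remaining level was 6.44% of wild type over the 5 genes and 3 kinds of library, but the genes were picked for their loss and RNA levels do not tell a deletion from silencing of the stretch. In nuclear RNA AT4G22290 had 0 mutant and 96 wild-type reads (at least 36.6-fold lower) and SOBER1 0 and 104 (at least 39.9-fold lower). In cytoplasmic RNA SOBER1 had 0 mutant and 33 wild-type reads (at least 10.8-fold lower), 27 of them in wild-type replicate 1. The lowest log2 fold changes of both fractions, −8.24 and −8.04, are fitted values of SOBER1 without mutant reads. A single mutant line was compared, so which changes come from ALY1 and which from other differences of that line was not tested.

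More transposable elements rose than fell, 66 against 12. Reads split into fractions between copies of a repeat are argued against as the whole cause. Of the 421 elements with whole values in all 6 libraries, 14 rose and 2 fell. Whole values cannot show a read with several places that was counted whole at 1 of them, so such reads stay open. The part of split reads stays open for the other 433, of which 52 rose and 10 fell: 12% rose, against 3.33%, but silenced repeats have copies in any case. An effect of 1 mutant library alone is argued against, since at least 79.4% of called elements rose with each mutant library left out. Background reads stay open. The risers' median gain was 409 times the mean mutant reads per element without wild-type reads, but only elements with far more reads than that mean could be tested and called. The 10 highest of those silent elements held 7.64% of their mutant reads, but only 5 of the 66 risers lie among them. The mutation itself stays among the open explanations, confounded with other differences of the line.

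Mutant total replicate 1 stood apart from the other mutant total libraries: without it 1639 genes passed, against 97 with it. It correlated across genes at 0.973, 0.977 and 0.975 with the wild-type total libraries and at 0.968 and 0.958 with mutant replicates 2 and 3. Its second principal component was −11.7, against −37.1 to −17.9 in wild type and 31.2 and 34.5 in mutant replicates 2 and 3. Whether replicate 1 or the other 2 differ for reasons other than genotype was not tested. Wild-type RNA in replicate 1 is argued against, since the 5 chromosome 4 genes together were at 2.4% of their wild-type level there. A different mix of bud stages stays open: the tapetum and pollen lists were lower in replicate 1 than in the other 2 (median −0.36, 15 of 17 lower, percentile 0 of 10000 matched lists). A heat or handling response also stays open: 8 of 8 heat shock genes were higher (median 1.1, percentile 100). The matched lists were drawn gene by gene, so the percentiles do not allow for genes of a list moving together. Mean deviations of the heat shock list ran from −2.02 to 1.63 in wild-type total libraries too. Those of the late pollen list were −0.95, 0.08 and 1.14 in mutant replicates 1 to 3. The percentiles therefore cannot decide either explanation, and the 2 were not told apart.

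The real grouping of the 6 total libraries gave 97 genes and 78 elements, and the highest count of the other splits was 0 for both. Only the real split, 1 of 10, gave as many genes or as many elements, and 10 splits cannot give a share under 0.05 (the smallest is 0.1).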

How the results depend on the processing

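Robust moderation, the export list without ALY1 and called genes read without a mutant fraction library were the tests chosen only after the result was seen. The count of 97 genes in total RNA was 543 with DESeq2, 428 with no filter, 187 with robust moderation and 41 with all 14 libraries in one fit, and 16 to 1639 with 1 library left out. The nuclear count of 8 was 29 with DESeq2, 143 with no filter, 17 with all 14 libraries and 0 with only the 4 libraries compared, and 3 to 157 with 1 library left out. The cytoplasmic count of 3 was 35 with DESeq2, 0 with limma-voom, 175 with no filter, 204 with all 14 libraries and 11 with only the 4 libraries compared, and 0 to 52 with 1 left out. The ratio count of 0 was 5 with no filter and 0 to 3 with 1 left out. Nucleus against cytoplasm gave 12312 genes in wild type and 12402 in aly1-2 with no normalization factors, and 7785 and 7714 with all 14 libraries. With 1 library left out these were 1610 to 4168 and 1767 to 3997. The element count of 78 was 130 with no filter and 51 to 155 with 1 left out. The causes were not tested.

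With no normalization factors the median of all genes moved from 0.024 to −0.168 in nuclear RNA and from 0 to −0.14 in cytoplasmic RNA, and that of the nuclear to cytoplasmic ratio from 0.053 to 1.64 in wild type and from 0.108 to 1.64 in aly1-2. This shift of all genes turned the sign of the log2 ratio in wild type for THO7B (0.25), PI (0.24), AP1 (0.15), FUL (0.19), LHCA4 (0.17) and NIMIN1 (0), and in aly1-2 for ALY1 (0.06), FDM2 (0.14), COR15A (0.18) and PRR3 (0.27), each still below the median of all genes. Over all named genes, 4544 of 5109 alternative values kept direction and side of the threshold, 469 lost the threshold and 71 gained it. Another 10, all just named, changed sign where the main or the alternative fit passed the threshold. A further 15 changed sign where neither fit passed. For gene lists, 322 of 381 were the same, 53 lost the threshold and 6 gained it.

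With the replicate number as a replicate block the counts were 20 in total, 19 in nuclear and 9 in cytoplasmic RNA, 0 for the ratio and 75 for elements, and a replicate block per genotype and number gave 1 for the ratio. The numbers did not pair the total libraries: deviations of same-numbered libraries correlated at −0.101, −0.235 and 0.261, and not every library correlated best with its own number. The correlations were 0.18 for nuclear, −0.024 for cytoplasmic, 0.034 within wild-type and 0.226 within mutant fractions. Leaving out elements that overlap genes was not run, since element coordinates were not used here. Where a fraction group was left with 1 library, it was assumed to vary like the other groups. Cytoplasmic depth in nuclear genes, 2.1 to 3.24 (1e6 counts), limits the fraction comparisons.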

Other observations

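The tests on abscisic acid genes and on neighbouring genes were written down before their results were seen, on patterns noticed in the data. Genes known from drought and abscisic acid responses were among those that fell in total RNA, and were named after their values were seen. LTI65 went from 89.6 ± 8.49 to 14.5 ± 6.14 CPM (SD, n = 3 each; edgeR log2 fold change −2.62, SE 0.27, adjusted p = 0.00916; 0.0725 without wild-type replicate 1). LEA7, a late embryogenesis abundant gene, went from 260.1 ± 40.9 to 56.2 ± 19.0 CPM (−2.21, SE 0.25, adjusted p = 0.0146; 0.106 and 0.0777 without wild-type replicates 1 and 2). Other such genes were less stable. HB-7 (−1.16, SE 0.19), LEA4-5 (−1.90, SE 0.25), TSPO (−2.48, SE 0.39) and MAPKKK18 (−1.30, SE 0.19) lost their calls without any 1 library other than mutant replicate 1, with adjusted p of 0.0719 to 0.199, 0.066 to 0.155, 0.0935 to 0.201 and 0.0586 to 0.157. HAI1 (−0.86, SE 0.13) lost its call without any wild-type replicate or mutant replicate 2 (0.11 to 0.174), and DI21 (−0.94, SE 0.10) without wild-type replicate 1 or 2 or mutant replicate 2 (0.0505 to 0.0783). RAB18, RD26 and HB-12, not called with all 6 libraries, passed in 1 of the 6 fits with a library left out, that without mutant replicate 1 (adjusted p = 0.000687, 0.0017 and 0.00314).

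One hypothesis was that the abscisic acid or drought response may be lower in the mutant buds. A list of other responsive genes, without the 1 called member HB-7, was lower in 18 of 24 cases in total RNA (median log2 fold change −0.51; camera p = 1.22e-06 with the preset correlation and p = 0.142 with an estimated one). The p with an estimated correlation was 0.0372 in nuclear and 0.117 in cytoplasmic RNA. In total RNA the other members of the list were positive: ERD10 (0.59), COR47 (0.41), KIN1 (0.63), KIN2 (0.51), ERD7 (0.74) and ABF2 (0.08). COR47 and KIN1 are also in the cold response list. The test of the abscisic acid list left the hypothesis undecided.

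A further hypothesis was that changes may be regional, affecting neighbouring genes together. Genes were taken as neighbours if no other tested gene lay between them, at any distance and with untested genes skipped. Without the 5 chromosome 4 genes, 2 such pairs changed in the same direction, against a mean of 0.208 in 10000 random sets (permutation p = 0.02). The pairs were AT1G33840 with AT1G33850 (log2 fold changes 4.94 and 4.48) and AT3G32043 with AT3G32195 (5.14 and 6.32). This count rests on calls that 1 library can end: AT1G33840 lost its call without wild-type replicate 1 or 3 or mutant replicate 2 (adjusted p = 0.0513 to 0.054), AT1G33850 without any wild-type replicate or mutant replicate 2 (0.0549 to 0.133). AT3G32043 lost its call without any wild-type replicate (0.0803 to 0.136), and AT3G32195 without any wild-type replicate or mutant replicate 2 (0.0733 to 0.136). With the chromosome 4 genes there were 6 pairs (permutation p = 0.0001, the smallest these sets can give). Distance, overlap or shared reads within the pairs were not tested.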
